A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

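RNA from 4 cultures of the knockout strain of *Halobacterium salinarum* NRC-1 was hybridised with a standard NRC-1 reference on 8 two-colour arrays, each RNA on 2 arrays with Alexa 532 and Alexa 647 exchanged. The deposited scanner tables give, per the file headers, a median intensity for each spot and its local background, in each dye and in a high-gain and a low-gain scan, with no background subtraction or normalization. The software and its settings are not given in the sources used here. The deposited tables also hold a confidence score per spot, which in these files was below its maximum only where a pixel was saturated, so no outlier flag was applied. The authors' value table was on a log10 scale with no description. Set against the scanner ratios, its columns followed log10 of Alexa 532 over Alexa 647 on every array, not turned for the exchanged dyes, with correlations across spots from -0.96 to -0.63 against Alexa 647 over 532. Its slopes, of log10 value on log2 scanner ratio, ran from -0.293 to -0.134, so part of their size is the change of log base. Their range and its column medians, from -0.02 to 0.13, leave the authors' centring and scaling unknown. Its rows carry no probe names. They were matched to scanner spots by an order of the print grid inferred from these same correlations, and the authors' own mapping is not given in the sources used here, so every value from this table rests on that match. It was used as an alternative, and 469 of the 10752 spots had no value in it.

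Direction was taken from the dyes in the labels. The median intensity of the high-gain scan was corrected by normexp with an offset of 50, and log2 ratios were normalized within each array by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Swapped arrays were turned so that each ratio is culture over reference, the 4 spots of a feature were averaged, and the 2 arrays of an RNA were averaged into 1 value. Arrays of 1 dye orientation correlated across features at r = 0.14 to 0.91, and the 2 arrays of an RNA at r = -0.42 to 0.48. The files mark no control spots, and all 2688 features were tested.

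A linear model with oxygen and light as additive terms was fitted to the 4 samples with lmFit and eBayes, leaving 1 residual degree of freedom (2.60 prior degrees of freedom were estimated), with Benjamini-Hochberg adjustment over features and a threshold of 0.05, two-sided. Its intercept, the mean over the 4 samples, gave the comparison with the reference. The reference counts as 1 control sample, and the test leaves out its own spread. Gene lists with at least 3 named genes were tested with camera at a preset correlation of 0.01, adjusted over the 9 lists. Of 23 lists, 9 were tested. No list passed with the preset or with an estimated correlation, which with 1 residual degree of freedom is poorly determined. A feature counted as above background when at least 2 of its 4 spots exceeded the local background by 1 SD of it, and as saturated when at least 2 reached 65535.

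Named genes were chosen by a rule set before the data were examined. It takes pyrF, afsQ2 and a set of rhodopsin, transducer, arginine fermentation, anaerobic respiration, gas vesicle and photolyase genes always, of which 9 were measured. It takes up to 10 genes in each direction past the threshold that keep 1 sign in both matched pairs and both dye orientations (on all 8 arrays for the reference), filled to 5 by size with genes said not to pass. It also takes up to 4 members of each list and the 5 largest oxygen-by-light differences in each direction among genes with 1 sign of it in both dye orientations. Names came from the platform annotation, which can be old. It gave 532 probes 1 symbol and 0 probes several, and 10220 probes are unnamed here. No coordinates are given.

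The steps were tested on simulated arrays with 200 of the 2688 features changed by 0.5, 1 or 2 log2. All features changed by 2 were called in each comparison (100%), and of those changed by 0.5 between cultures and reference 71.6%. Unchanged features were also called, 15 between cultures and reference, 5 for oxygen and 7 for light. Between cultures and reference these 15 stood beside 48, 67 and 66 changed features called at 0.5, 1 and 2 log2. The simulation gave all features a common spread between RNAs and between spots. It also gave each feature the same dye effect on every array. Real arrays need not behave so, and these shares are not the power of this experiment. Alternatives covered background correction, normalization, filters on dim and saturated spots, spot summary, the deposited value table, the variance model, arrays in place of samples, the dye orientation as a block, and leaving out each array and each RNA. Print-tip loess, merged scans, features above background on all arrays, the centred value table, each dye orientation alone, lists without pyrF and panB, and 8 further gene lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9.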

Results

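Transcript levels were measured in *Halobacterium salinarum* NRC-1, a salt-loving archaeon that grows with oxygen or on light through rhodopsin proton pumps. The strain lacked ura3, the orotidine phosphate decarboxylase gene used as a selectable marker in this organism, and afsQ2. It was grown to mid-log phase in rich medium, in 50 mL of culture in a 125 mL flask, with high oxygen (shaking at 210 RPM) or low oxygen (stoppered, 100 RPM), each in light or in a flask kept dark. Each of the 4 conditions gave 1 RNA sample. Each RNA sample was hybridised on 2 arrays with the dyes exchanged, Alexa 532 and Alexa 647, against a standard mid-log RNA of NRC-1, so that the 8 arrays stand for 4 samples. The arrays carried 2688 features with 4 spots each. Gene names were at hand for 133 features and the other 2555 are unnamed here. Both channels were above background on all 8 arrays for 909 features, 77 of them named. Between 41.1% and 75.0% of features were above background in Alexa 532 and between 44.4% and 77.4% in Alexa 647. The number of arrays limits the precision of every value. With 1 RNA sample per condition, p-values and SEs do not measure the spread between replicate cultures. They rest on what the oxygen and light terms leave unexplained in these 4 samples. That remainder is the oxygen-by-light difference, moderated across features.

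The deleted genes were looked at first. The name ura3 is not among the named features, and pyrF, a name of the same enzyme's gene, was taken to be it. The deleted part of the gene and the probe's place in it are not given in the sources used here, and a probe outside the deletion would check nothing. pyrF had a mean log2 ratio of culture over reference of -0.68 (SE 0.06, SD 0.28, n = 4 RNA samples; limma adjusted p = 0.0274). With the culture in Alexa 532 the 4 arrays gave -0.29, 0.02, -0.48 and 0.06 for high oxygen in light, high oxygen in dark, low oxygen in light and low oxygen in dark. With the culture in Alexa 647 the same RNAs gave -1.50, -1.01, -1.39 and -0.84. The pyrF spots were not well above background on any of the 8 arrays in the reference channel, and were above it on 1 array in the culture channel, so no fold is given and the value does not check the labels. No named feature carried afsQ2, and its level was not analysed here.

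The cultures were then compared with the reference, a comparison in which strain and growth conditions cannot be separated. Of the named genes, 4 fell on all 8 arrays and passed the test. *phoU*, a regulator of phosphate uptake, fell by 0.68 on the log2 scale (SE 0.11, adjusted p = 0.0391). *rpmC*, for ribosomal protein L29, fell by 0.56 (SE 0.07, adjusted p = 0.0320), and *rpl12p*, for another protein of the large ribosomal subunit, fell by 0.51 (SE 0.06, adjusted p = 0.0310). *citZ*, for citrate synthase, the entry enzyme of the tricarboxylic acid cycle, fell by 0.40 (SE 0.06, adjusted p = 0.0387). All 4 were above background in both channels on all 8 arrays, with n = 4 RNA samples in each limma test. The *rpl12p* spots were saturated on 4 arrays in the culture channel and on 6 in the reference channel, so the size of its fall is uncertain. With the low-gain scan merged in at saturated spots, an alternative chosen after seeing the data, *rpl12p* stood at -0.77 (adjusted p = 0.0224), and it was at -0.82 with median centring and -0.90 in the deposited value table. *phoU* and *citZ* passed in 17 of 31 alternatives that changed any value, *rpmC* in 18 of 31 and *rpl12p* in 17 of 30, and in the following none of the 4 passed. They were plain background subtraction, print-tip loess, the 8 arrays taken as independent, the arrays of either dye orientation alone, leaving out the RNA of low oxygen in light or of low oxygen in dark, and leaving out any single array other than the Alexa 647 arrays of high oxygen in dark and of low oxygen in light.

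*gyrB*, a subunit of DNA gyrase, also lay below the reference on all 8 arrays (log2 -0.48, SE 0.09, adjusted p = 0.0526) and did not pass. Unlike those 4 genes, *gyrB* was not above background in both channels on all 8 arrays. No named gene passed above the reference with 1 sign on all 8 arrays. The only named gene above 0 on all 8 was *arcC*, for the carbamate kinase of arginine fermentation (log2 0.31, SE 0.07, adjusted p = 0.0676), which did not pass. Altogether 10 of the 133 named genes passed, 4 higher and 6 lower. The higher ones were *hutI*, *gatC*, *mamA* and *purB*, none of them above background on any array in the reference channel, so their sizes are not given. In the culture channel *mamA* was above background on 0 arrays, *purB* on 1, and *hutI* and *gatC* on 2 each. The means of *gatC* and *purB* were above 0 with the culture in Alexa 532 and below 0 with it in Alexa 647, so their direction followed the dye. *gdhA1*, for a glutamate dehydrogenase, was lower (log2 -0.38, SE 0.06, adjusted p = 0.0456) on 7 of the 8 arrays, and pyrF is described above. *hutI*, *gatC*, *mamA*, *purB* and *gdhA1* were named here after their values were seen.

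**Figure D1:**
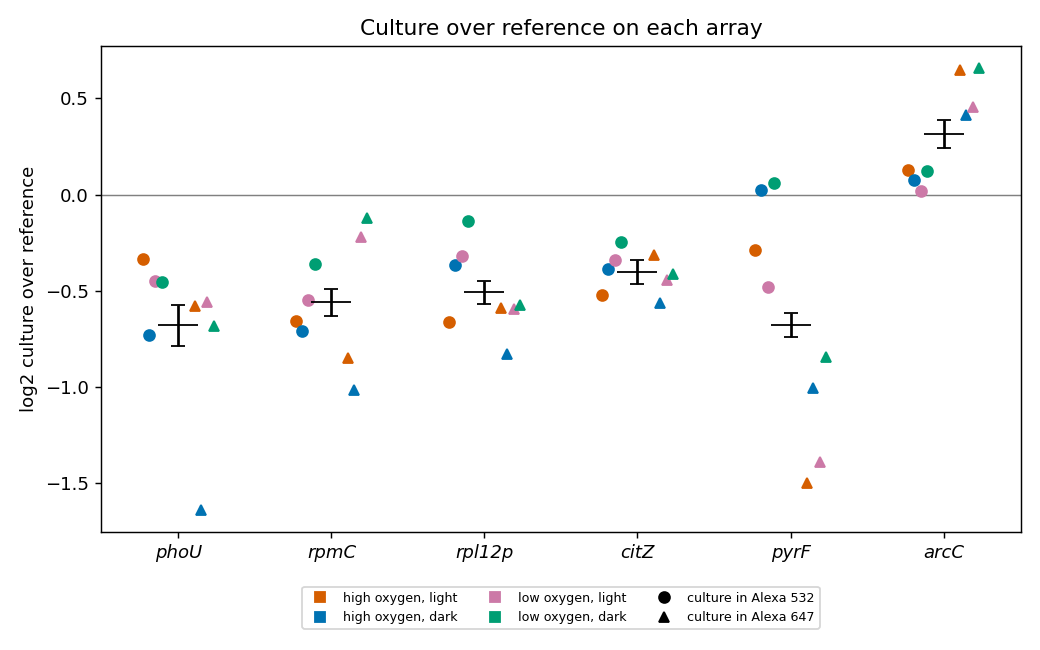
Log2 culture over reference for 6 genes on each of the 8 arrays. Colours are the 4 conditions, and circles and triangles the arrays with the culture in Alexa 532 and Alexa 647. Black bars are the mean of 4 RNA samples with its SE from the limma fit. *phoU*, *rpmC*, *rpl12p* and *citZ* lie below 0 on all 8 arrays, while pyrF lies between -0.48 and 0.06 in one dye orientation and between -1.50 and -0.84 in the other.

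Among the gene lists, the tricarboxylic acid cycle list was lowest. All 5 measured members were below the reference, with a median log2 of -0.24. Over all features 1 member passed (*citZ*), and 3 passed adjusted over the list alone, *citZ*, *sucC* (log2 -0.33, succinyl-CoA synthetase) and *mdh* (log2 -0.24, malate dehydrogenase). The list itself did not pass (camera adjusted p = 0.0723, and adjusted p = 0.561 with an estimated correlation). It passed with median centring (adjusted p = 0.0198), in the deposited value table (adjusted p = 6.38e-05), whose rows were matched to spots by an inferred order, and among features above background on all arrays (adjusted p = 0.0434). All 3 members of the glycolysis list lay below the reference, led by *tpiA* (log2 -0.19), and none passed (list adjusted p = 0.300, and adjusted p = 0.0311 in the value table). In pyrimidine synthesis all 5 members lay below it, with pyrF the 1 member that passed over all features and adjusted over the list alone. *carB* and *carA*, for carbamoyl phosphate synthase, were at -0.23 and -0.18 (list adjusted p = 0.145). This list passed with median centring (adjusted p = 0.0350) and in the value table (adjusted p = 0.0153), and without pyrF it stood at a median of -0.11 (adjusted p = 0.310). Of 4 cobalamin synthesis genes 3 were below 0, with *cbiT* at -0.34 and *cbiG* at -0.23, and none passed (list adjusted p = 0.234, and adjusted p = 0.00236 in the value table). Of 11 flagella and chemotaxis genes 9 were above 0, among them the transducer genes *htr7* (0.20) and *htr4* (0.19) and the methylesterase gene *cheB* (0.18), and none passed (list adjusted p = 0.234). Of these 11 genes 7 were above background on all arrays.

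Of the 5 genes of sensory rhodopsins, halorhodopsin and their transducers none passed, with *sop1* at 0.09, *sop2* at -0.09, *htr1* at 0.06, *htr2* at -0.07 and *hop* at 0.27, the last above background on 1 array in the reference channel (list adjusted p = 0.743). The lists of chaperones and proteasome (*psmA* -0.18, *dnaK* -0.14; adjusted p = 0.300), DNA repair (*uvrB* 0.15; adjusted p = 0.580) and DNA replication (*gyrB* -0.48, *gyrA* -0.21; adjusted p = 0.300) did not pass, though *gyrB* passed adjusted over the list alone. The name panB, in the chaperone list, usually stands for an enzyme of pantothenate synthesis. Lists with 1 or 2 named genes were not tested. Of these, *bat*, a regulator of bacteriorhodopsin, was at 0.34 but not above background in the reference, *arcA* was at 0.08, *moaC* at 0.21, *sdhC* at 0.04, *nuoL* at 0.03, *msrA* at 0.14 and *dpsA* at 0.03, and none of them passed. *rpl12p* was the measured ribosomal protein of its list and *phoU* that of phosphate uptake. Another 7 lists had 0 named genes here: carotenoid synthesis, gas vesicles, ATP synthase, RNA polymerase, potassium and metal transport, kinases and regulators, and amino acid transport.

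Over all 2688 features, limma called 265 higher and 109 lower than the reference at an adjusted p below 0.05. Of these calls, 238 of the higher and 92 of the lower were not above background throughout. Across features, the log2 ratios to the reference correlated between the dye orientations at r = 0.10, with 58.6% of features keeping their sign. The correlation was r = 0.17 over the 909 features above background and r = -0.06 over the 133 named genes. Of the 374, 120 had 1 sign on all 8 arrays, and 37 of these were above background throughout, 24 higher and 13 lower. Among these the unnamed features with probe IDs 4805 (log2 0.80) and 197 (log2 -0.82) changed most. The counts and the share of higher calls differed with the treatment of background and scale. Plain background subtraction, which left 2129 features to test, gave 0 higher and 0 lower (smallest adjusted p = 0.156). The counts were 270 higher and 271 lower without background subtraction, 545 and 553 with median centring, 190 and 150 without the dimmest features, 527 and 398 with an intensity trend, 32 and 79 in the deposited value table, and 124 and 172 among the 909 features above background. Leaving out the RNA of low oxygen in light or of low oxygen in dark left 0 calls, as did leaving out the array of high oxygen in light with the culture in Alexa 647, of high oxygen in dark in Alexa 532, or either array of low oxygen in dark. Without the Alexa 532 array of high oxygen in light the counts were 0 higher and 1 lower, and without that of low oxygen in light 63 and 4, while leaving out the Alexa 647 array of high oxygen in dark gave 418 and 279, that of low oxygen in light 420 and 254, and the RNA of high oxygen in light 538 and 480.

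For oxygen, low was set against high, with 2 RNA samples on each side. No gene passed. The largest rises with 1 sign in both matched pairs and both dye orientations were *rpmC* (log2 0.50, SE 0.14), *purD* of purine synthesis (0.47, SE 0.17), *gdhA1* (0.35, SE 0.13), *carB* (0.33, SE 0.12) and *infB*, for a translation initiation factor (0.30, SE 0.18), each with a limma adjusted p of 0.795. The value of *infB* was 0.05 in light and 0.55 in dark. Without the Alexa 647 array of high oxygen in dark, *purD* was at 0.23, *gdhA1* at 0.22, *infB* at 0.15 and *rpmC* at 0.42. *rpmC* stood at -0.81 against the reference in high oxygen and at -0.31 in low oxygen. On the other side were *gatC* (-0.44, SE 0.17), *purB* (-0.43, SE 0.13), *tmk* (-0.36, SE 0.16), *deoC* (-0.34, SE 0.16) and *gyrA* (-0.33, SE 0.14), also at 0.795, and of these only *gyrA* was above background on all 8 arrays. Without that same array *gyrA* was at -0.17, and leaving out 1 array in turn gave -1.41 to 0.53 for *gatC* and -1.01 to 0.16 for *purB*. For *deoC* the range was -0.61 to -0.07, and for *tmk* it was -0.51 to -0.21.

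*arcA* and *arcC* of arginine fermentation were at -0.04 (SE 0.13) and 0.00 (SE 0.14) for low against high oxygen. These are means of opposite values, -0.14 in light and 0.07 in dark for *arcA*, and -0.15 and 0.15 for *arcC*. *moaC*, of the molybdenum cofactor, was at -0.17 (SE 0.15). *sdhC* and *nuoL* of the aerobic respiratory chain were at 0.07 (SE 0.15) and 0.00 (SE 0.12), and *bat* was at -0.02. *rpl12p* was at 0.21, *phoU* at 0.28, *msrA* at 0.10 and *dpsA* at -0.05. In the rhodopsin list 4 of 5 genes were below 0, with *hop* at -0.27 and *sop1* at -0.12, against *sop2* at 0.12 (camera adjusted p = 0.673). All 4 DNA repair genes were below 0, with *radB* at -0.25 and *uvrB* at -0.16 (adjusted p = 0.389), and 9 of 11 flagella and chemotaxis genes, with *htr18* at -0.30 and *htr6* at -0.29 (adjusted p = 0.419). Above background on all arrays were 1 of these 4 DNA repair genes and 7 of these 11 flagella and chemotaxis genes. Of 6 chaperone and proteasome genes 5 were above 0, with *dnaK* at 0.25 and *psmA* at 0.19 (adjusted p = 0.522). The pyrimidine list stood at a median of 0.03 (adjusted p = 0.673), and the glycolysis, tricarboxylic acid cycle, cobalamin and DNA replication lists at medians of 0.01, 0.01, 0.03 and 0.00 (each adjusted p = 0.879). In the tricarboxylic acid cycle and replication lists the mean and the test were below 0 while the median was above. No member of any list passed, over all features or adjusted over the list alone.

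The limma count was 0 of 2688 features, with 123 at an unadjusted p below 0.05 where chance gives 134. Across features, which are not independent replicates, the oxygen effect in one dye orientation correlated with that in the other at r = 0.08 over all 2688 and at r = 0.34 over the 909 features above background. In simulated arrays of this design 67.2% of features changed by 1 log2 between oxygen levels were called and 5.97% of those changed by 0.5. The simulation used a common spread for all features, so these shares may not hold for the real arrays.

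**Figure D2:**
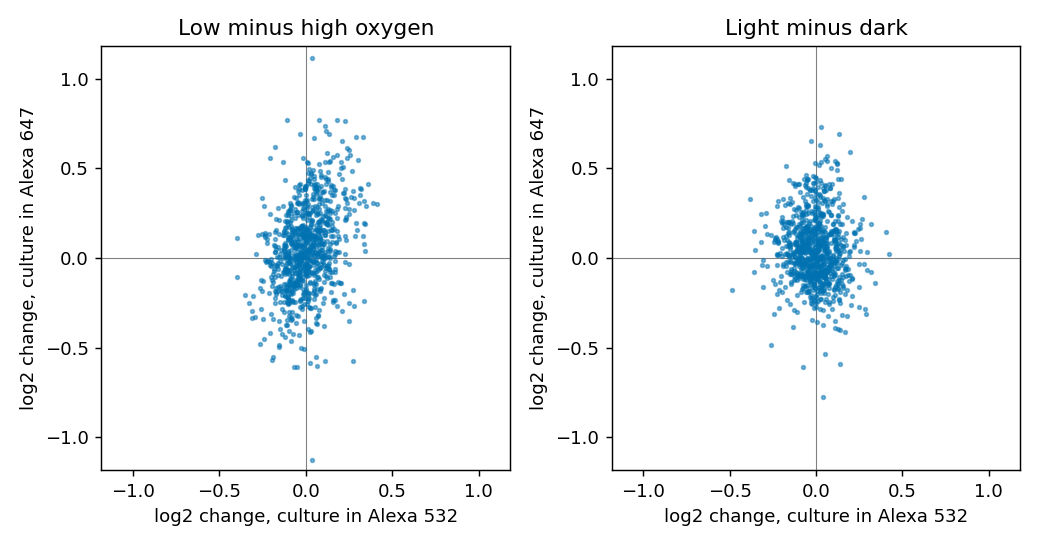
Each point is 1 of the 909 features above background on all arrays; the x axis is the log2 change on the arrays with the culture in Alexa 532 and the y axis that with the culture in Alexa 647, for low minus high oxygen (left) and light minus dark (right). The oxygen values correlate at r = 0.34 across features and the light values at r = -0.06.

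For light, light was set against dark, again with 2 RNA samples on each side. No gene passed. Among named genes with 1 sign in both matched pairs and both dye orientations, *mch* had the largest value, -0.63 (SE 0.12, limma adjusted p = 0.997), and was above background on 2 arrays in the culture channel and 1 in the reference. It was followed by pyrF (-0.47, SE 0.13), *glyS* (-0.34, SE 0.16), *tmk* (-0.33, SE 0.16) and *gatC* (-0.29, SE 0.17), none of them above background on all arrays. Above 0 were *phoU* (0.39, SE 0.21), the proteasome gene *psmA* (0.32, SE 0.20), *hutU* (0.32, SE 0.19), the chaperone gene *dnaK* (0.29, SE 0.16) and *purD* (0.23, SE 0.17). Each of these had an adjusted p of 0.997. Light less dark was 0.73 in high and 0.06 in low oxygen for *phoU*, 0.62 and 0.03 for *psmA*, 0.60 and 0.04 for *hutU*, 0.48 and 0.10 for *dnaK*, and 0.46 and 0.00 for *purD*. Much of this lay on 1 array, that of high oxygen in dark with the culture in Alexa 647, without which *phoU* was at 0.17, *psmA* at 0.12, *dnaK* at 0.20, *purD* at -0.01, *mch* at -0.27 and *glyS* at -0.04. The *hutU* spots were above background on 0 arrays in either channel, and leaving out 1 array in turn gave -0.34 to 0.98 for *hutU* and -1.26 to 0.68 for *gatC*. The range was -0.78 to -0.17 for pyrF and -0.48 to -0.18 for *tmk*. Without the Alexa 647 array of high oxygen in dark pyrF moved away from 0, to -0.73.

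The light-sensing genes did not differ between light and dark beyond their error. *sop1* and *sop2*, for sensory rhodopsins I and II, were at 0.09 (SE 0.12) and 0.03 (SE 0.12), their transducers *htr1* and *htr2* at -0.04 (SE 0.12) and -0.02 (SE 0.15), and *hop*, for the chloride pump halorhodopsin, at -0.14 (SE 0.16), with a camera adjusted p of 0.959 for the list. *bat* was at 0.18 (SE 0.13), and was above background on 1 array in the culture channel and 0 in the reference. Without the Alexa 647 array of high oxygen in dark it was at -0.01, and without the Alexa 532 array of that RNA at 0.38. *arcA* was at 0.07, *arcC* at -0.01, *moaC* at -0.05, *sdhC* at 0.13, *nuoL* at -0.04, *rpl12p* at -0.07, *msrA* at 0.04 and *dpsA* at -0.02. The DNA repair list had 3 of 4 genes below 0, with *radB* at -0.28 and *mutL* at 0.22, and the pyrimidine list 4 of 5 above 0, with *carB* at 0.18. Only 1 of the 4 DNA repair genes was above background on all arrays. Flagella and chemotaxis genes were divided, 6 above 0 and 5 below, with *cheY* at 0.23 and *htr18* at -0.28, and the test pointed below 0 while the median and mean were above. The lists of chaperones, the tricarboxylic acid cycle, glycolysis, cobalamin synthesis and DNA replication had medians of 0.01, 0.03, 0.00, -0.03 and 0.05. The adjusted p was 0.959 for all 9 lists, and no member passed over all features or adjusted over the list alone.

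By limma 0 of 2688 features passed, and 118 had an unadjusted p below 0.05 where chance gives 134. Across features the dye orientations correlated at r = -0.07 for the light effect, and at r = -0.06 over the 909 above background. In simulated arrays 80.6% of features changed by 1 log2 between light and dark were called and 2.99% of those changed by 0.5. The simulation used a common spread for all features, so these shares may not hold for the real arrays. There the largest light value was 1.67 log2, and the smallest limma adjusted p over all features was 0.997.

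**Figure D3:**
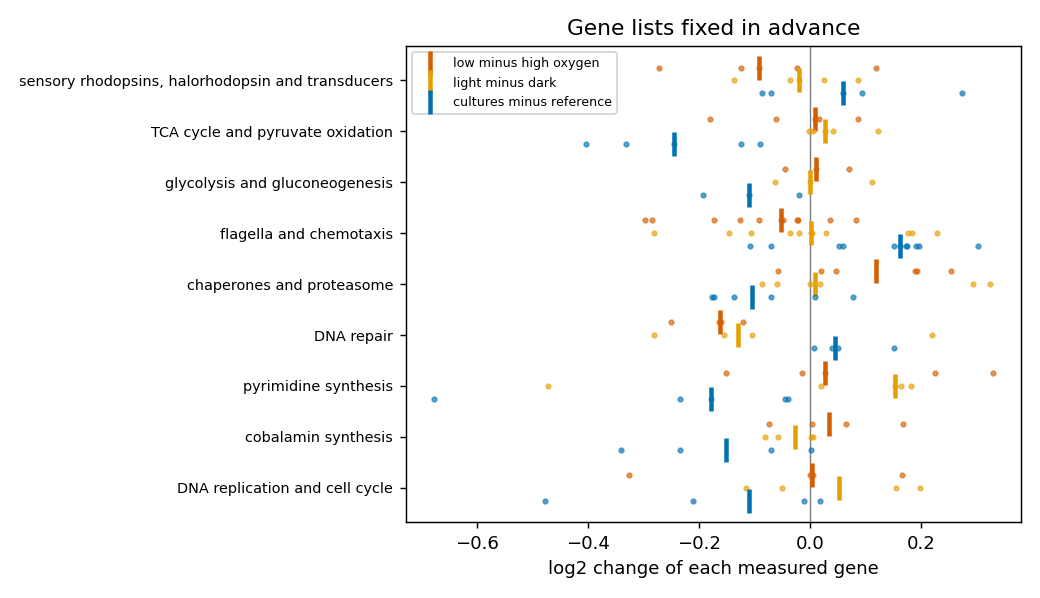
Log2 change of each measured gene (points) and the median (bars) in 9 gene lists, for low minus high oxygen, light minus dark, and cultures minus reference. The 5 tricarboxylic acid cycle genes all lie below 0 against the reference, with a median of -0.24, and no list passed the test in any of the 3 comparisons.

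Whether the oxygen effect differed between light and dark can be given only as values. The 4 samples leave no spread for this difference, and it serves as the error of the other tests. Among named genes with 1 sign of this difference in both dye orientations, the effect in light exceeded that in dark most for *nadA* (by 0.88 on the log2 scale), *nadC* (0.64), *purM* (0.50), *hisF* (0.46) and *hop* (0.41), the first pair being genes of NAD synthesis. It was below that in dark for *thiL* (-0.98), *proS* (-0.71), *guaB* (-0.69), *phoU* (-0.66) and *cca* (-0.63). With the culture in Alexa 532 and in Alexa 647 the difference was -0.20 and -1.77 for *thiL*, -0.29 and -1.10 for *guaB*, -0.39 and -0.94 for *phoU*, -0.29 and -0.98 for *cca*, and 0.17 and 1.11 for *nadC*. On the Alexa 647 array of high oxygen in dark *thiL* stood at -2.00 against the reference, and on the other 7 between -0.51 and 0.01. Of these 10, *guaB* and *phoU* were above background on all 8 arrays in both channels. Over all features 53 had a difference of at least 1 log2 with 1 sign in both dye orientations, 18 positive and 35 negative, and 0 of the 53 were above background throughout. Across features this difference correlated between the dye orientations at r = -0.61 over all features and at r = -0.01 over those above background, so over all features it tended to run opposite in the 2 orientations.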

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

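Of the tests in this part, those of print-tip position and of pyrF among features of like intensity were chosen before their results were seen, and those of dim spots, a response to oxygen, deletion, intensity-dependent bias and saturation after.

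The 4 RNA samples of *phoU* included 1 far from the rest, high oxygen in dark, with a log2 ratio against the reference of -1.18 where the others lay between -0.57 and -0.46. Its 2 arrays gave -0.73 with the culture in Alexa 532 and -1.64 with it in Alexa 647. The other RNAs gave -0.34, -0.45 and -0.45 in Alexa 532, so this RNA was lowest there too. On its Alexa 647 array *purD* (-1.18), *thiL* (-2.00) and *guaB* (-0.84) were also lower than on any other. The size of the *phoU* value therefore cannot be assigned to the RNA rather than to that array. Of 14 genes looked at, 1 was flagged this way, and chance alone flags a share of about 0.05.

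For 7 of 36 genes looked at the oxygen effect had opposite signs in light and in dark, each with 1 sign in both dye orientations. These differences were not tested, since 1 RNA sample stands behind each condition. *thiL*, *proS*, *guaB* and *cca* were named for the size of this same difference, so the count of 7 says nothing about how often such genes occur. The effect in light less that in dark was 0.32 for *htr2*, -0.22 for *arcA*, -0.29 for *arcC*, -0.98 for *thiL*, -0.71 for *proS*, -0.69 for *guaB* and -0.63 for *cca*.

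The falls of *phoU*, *rpmC*, *rpl12p* and *citZ* against the reference were weighed against technical explanations. Dye bias was not tested, since the genes were chosen for 1 sign on all arrays, but each mean holds both orientations equally, so that a constant dye effect cancels in it by design. Loess, which removes a trend with intensity, left at least 0.621 of each median-centred fall. The 4 genes were chosen from the loess values for passing the threshold. Their passing after loess was therefore fixed in advance, and this test cannot decide whether such a trend is the cause. For *rpl12p* the reference was saturated on more arrays than the cultures, which would make a fall look smaller. Merging in the low-gain scan enlarged the fall, to -0.77 or 1.51 times its value. With the reference saturated on more arrays, merging was bound to enlarge the fall, so this test cannot decide whether saturation is its cause. The size of the *rpl12p* fall stays uncertain. Strain, culture conditions and the single reference RNA stay open and untested.

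pyrF was lower mainly where the culture carried Alexa 647, by -1.01 relative to the arrays with Alexa 532. Among the 200 features nearest in intensity this difference lay at percentile 7, within the range of dim features, but their median was 0.34, in the other direction. Dye bias of dim spots therefore cannot be told apart from other causes of the difference between orientations. Deletion of the gene predicts less signal than the reference, but the reference was above background on 0 of 8 arrays, so deletion of the gene cannot be told apart from background.

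The light effect did not carry over between dye orientations. Among features above background r across features was -0.0553, so the lack of agreement was not limited to dim features. After print-tip loess r was -0.0281 over all features. If light changed few transcripts, r would stay low whatever the artefact, so these values cannot exclude dim spots or position on the slide as a cause. For oxygen, r was 0.342 among features above background and 0.0454 among the rest, so dim spots may hide agreement there. The oxygen correlation exceeded the higher of the other 2 contrasts of the same 4 RNAs by 0.354, consistent with a response to oxygen below the threshold in abundant transcripts. With 3 contrasts and 1 RNA per condition, a difference between single cultures stays open.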

How the results depend on the processing

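Each dye orientation alone, print-tip loess, merged scans, features above background, the centred value table and the changed lists were chosen after seeing the data. The oxygen and light counts were 0 features under all alternatives run, and 0 lists passed for either under those run on lists. Leaving out each array or RNA in turn also gave 0 for both. Against the reference, with 265 higher and 109 lower, the counts were 270 and 271 without background subtraction, 0 and 0 with plain subtraction, 545 and 553 with median centring, 190 and 150 without the dimmest features, 32 and 79 in the value table (56 and 135 when centred), 527 and 398 with an intensity trend, 441 and 251 with neither factor, 88 and 35 with print-tip loess, and 124 and 172 among features above background on all arrays. With 8 arrays in place of 4 samples they were 704 and 664 with the RNA as a random block, 0 and 2 as independent arrays, and 79 and 43 with the dye orientation as the replicate block, where pairing is by dye and not by culture. In the random-block fit the estimated correlation between the 2 arrays of an RNA was -0.625. A negative value makes the mean of a pair count as more precise than that of independent arrays. The main fit also used the mean of each pair. Its error, the oxygen-by-light difference, tended to run opposite in the 2 orientations over all features (r = -0.61). It therefore partly cancels in those means, which makes the error smaller. Over features above background r was -0.01. Arrays with the cultures in Alexa 532 alone gave 0 and 0, as did those in Alexa 647. Leaving out 1 array or RNA gave 0 to 538 higher and 0 to 480 lower; an array left out leaves 1 RNA with a single dye, and the cause of the other differences was not tested. Aquantile scaling after loess repeated every value and is not counted here. *phoU* and *citZ* were below the reference in 31 of 31 alternatives and passed in 17, *rpmC* was below in 31 and passed in 18, and *rpl12p* was below in 30 of 30 and passed in 17. These genes were chosen for lying below the reference on every array. Alternatives that only drop or average again the same array values therefore had to leave them below it. Lists past the threshold against the reference rose from 0 to 2 with median centring, 4 in the value table and 1 among features above background. The log2 ratio of pyrF was -0.34 without background subtraction, -1.36 with plain subtraction, -0.26 in the value table, -0.17 on Alexa 532 arrays and -1.19 on Alexa 647 arrays, and -0.83 to -0.53 without 1 array. Oxygen-by-light differences of at least 1 log2 numbered 20 without background subtraction, 234 with plain subtraction, 29 with median centring, 14 without the dimmest features, 25 in the centred value table, 0 among features above background, and 75 to 276 without 1 array, where 1 orientation alone sets the sign. On all arrays 909 of 2688 features exceeded background, and low signal limits the values of the others.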

Other observations

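All tests in this part were chosen after the data were seen, on 8 gene lists made from the named genes and adjusted over the 8 in each comparison. The histidine breakdown genes *hutI*, *hutG* and *hutU* were above background on 0 arrays in the reference channel, so no size is given against the reference. The mean of *hutU* was above 0 with the culture in Alexa 532 and below 0 with it in Alexa 647. The 3 genes passed adjusted over the list alone and *hutI* also over all features, but the list did not pass (camera adjusted p = 0.334, and adjusted p = 0.635 with an estimated correlation). Histidine synthesis genes were below the reference in 5 of 6 cases (median -0.03, adjusted p = 0.464), and 1 of the 6 was above background on all arrays. Glutamate metabolism genes were below it in 3 of 4 (median -0.17, adjusted p = 0.347), of which 2 passed adjusted over the list alone, and all 3 protein export genes were below it (median -0.05, adjusted p = 0.464).

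Aminoacyl-tRNA synthesis genes were below the reference in 9 of 14 cases (median -0.07, adjusted p = 0.347) and purine synthesis genes in 5 of 7 (median -0.13, adjusted p = 0.464), and the member of each that passed, *gatC* and *purB*, was dim and had means of opposite sign in the 2 dye orientations. Chemoreceptor genes, which the flagella and chemotaxis list also holds, had a median of 0.15 (adjusted p = 0.464), and thiamine synthesis genes a median of 0.03 with a mean of -0.12 and a test below 0 (adjusted p = 0.698). Of the 7 chemoreceptor genes 3 were above background on all arrays. For oxygen, purine synthesis genes were above 0 in 5 of 7 cases, with a median of 0.22 (adjusted p = 0.533), and histidine breakdown genes, all dim, did not pass (adjusted p = 0.533). For light, 5 of 6 histidine synthesis genes were below 0 (median -0.09, adjusted p = 0.416), with 1 of the 6 above background on all arrays. None of the 8 lists passed in any of the 3 comparisons.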
